A study of Mus musculus with 10 samples.

How the data were processed

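The data were RNA sequencing counts of 10 mouse lung libraries in 3 APE1 genotypes. About 500 premalignant cells were lysed per library, the cDNA was amplified by a modified SMART-Seq2 protocol, and 1 ng of cDNA went into a tagmentation library kit, per the labels' protocols. Reads were trimmed with Trim Galore 0.5.0, aligned to mm10 with HISAT2 2.1.0 and counted with featureCounts 1.6.4, and DESeq2 was named without a version, per the submitters' processing notes. The deposited values were raw read counts per gene, whole numbers with no normalization, in 1 table of 25277 gene symbols. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping or antisense genes, of paralogs and of pseudogenes are therefore uncertain. Of the symbols, 24418 (96.6%) were found in GENCODE M21, from which coordinates on GRCm38 were taken. All columns matched a sample's label, and none was left over. No mitochondrially encoded gene of the list made for them was in the table, so that share was not analysed here.

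Genotypes and replicate numbers came from the labels. A chi-square comparison of replicates found no pair that agreed within sampling noise, so every library counted as 1 sample. The reads carried no molecular identifiers, so floors of 3 counts per library cover counting error only. The test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The separation of libraries by Xist and Y-linked genes was read from the counts.

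Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr on genotype, which left 13464, libraries were scaled by TMM factors, and a quasi-likelihood model with genotype as its only term was fitted to all 10 libraries, so that the genotypes shared 1 estimate of the spread. Each of the 3 comparisons was tested two-sided with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The common dispersion was 1.53, a biological coefficient of variation of 1.24. CPM values are counts scaled by the TMM-adjusted totals to the usual unit and are given as mean ± SD. Medians of lists are differences of mean log2 CPM with a prior count of 2. Over all genes, edgeR log2 fold changes had medians of 0.056, -0.045 and -0.11 for the 3 comparisons in the order that follows. A value relative to all genes therefore depends on the measure. TMM, DESeq2 size factors and plain totals gave median differences over all genes of -0.62, -0.72 and -0.73 for flox/flox against flox/+, of 0.15, 0.18 and 0.24 for flox/N211A against flox/+, and of 0.85, 0.98 and 1.04 for flox/N211A against flox/flox.

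There were 38 gene lists (pathways, markers of lung and other cell types, and quality lists), of which 35 had at least 5 members tested. They were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. Camera compares a list with all other genes. With the correlation estimated per list, 0 lists were called in any comparison, with a lowest adjusted p of 0.885, 0.415 and 0.865, so none of the calls holds with an estimated correlation. Fry, which tests whether a list's genes move in 1 direction and makes no comparison with other genes, called 4, 0 and 0. Members were also adjusted over their list alone.

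Named genes were Apex1, the urea cycle genes, per comparison the genes with the largest changes past the threshold, at a mean of at least 10 CPM in 1 genotype and without overlap of the libraries, leaving out clone names, and up to 4 members of each list described. Among the list members that the rule picks in flox/N211A against flox/+, 1 is not reported here. Where fewer than 5 genes passed in a direction, up to 5 with the smallest p that met the other terms were taken and given as values that did not pass. After the results were seen, the lists described with members were limited to those called in the comparison and the urea cycle list, and the direction of a list under an alternative was read from its median. Genes named outside this rule are said to be chosen after their values were seen.

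The alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE size factors, plain totals, no low-count filter, a filter of 10 CPM in 3 libraries, only the libraries of the 2 genotypes compared, the replicate number as a block, the number of genes detected or the Xist and Y-linked split as a term, a 2-fold minimum, an adjusted p under 0.1, a prior count of 0.5, an estimated correlation, fry, and each library left out in turn. Leaving out flox/flox replicates 2 and 3 together, and the terms for sex and for genes detected in the tests of gene lists, were added after the data were seen. With those 2 libraries left out the lone flox/flox library is assumed to vary like the other genotypes. DESeq2 gave no adjusted p for 956 genes in each comparison with flox/flox and for 715 in flox/N211A against flox/+, and these were left as missing.

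The procedure was tested on simulated data with the means, totals and dispersions of these libraries and 100 genes changed at each fold. For flox/flox against flox/+, with 12830 genes run, 2% of the genes changed 4-fold and 25% of those changed 16-fold were called, with 1 false call. For flox/N211A against flox/+, with 12909 genes run, these were 4% and 23% with 3 false calls, and for flox/N211A against flox/flox, with 12879 genes run, 1% and 27% with 2. With dispersions at 0.1 of these values, 59%, 66% and 62% of the 4-fold genes and 91%, 97% and 93% of the 16-fold genes were called in the same order. In 10 simulated runs of flox/flox against flox/+, 0 of 346 unchanged list tests were called and a 4-fold shift of the alveolar type II and ciliated lists was called in 10 runs each. Simulated genes were independent, unlike real ones. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.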

Results

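Gene expression was measured by RNA sequencing in 10 libraries of mouse lung cells that the labels call premalignant, each made from about 500 cells with a modified SMART-Seq2 protocol, which copies full-length transcripts and amplifies them by PCR. The animals had received an adenovirus carrying the Cre recombinase 12 wk before. The libraries came from 3 APE1 genotypes. APE1, encoded by Apex1, is the apurinic/apyrimidinic endonuclease of base excision repair, and Cre removes an allele that is flanked by loxP sites (flox). The control genotype flox/+ had 4 libraries, flox/flox had 3, and flox/N211A, which carries the mutant allele N211A beside a flox allele, had 3. Total counts ran from 13221853 to 17707731 in flox/+, from 10672334 to 53678659 in flox/flox and from 8955368 to 17070817 in flox/N211A. Of 25277 genes, 13464 had enough counts to be tested.

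Flox/flox replicates 2 and 3 stood apart from the other 8 libraries. Their rank correlations with other libraries lay between 0.671 and 0.782, while those among the other 8 lay between 0.811 and 0.924. In flox/flox replicate 2, 34.2% of the tested genes had 0 counts, against 2.82% to 16.6% in the other 9 libraries. The 45S ribosomal RNA gene Rn45s took 2.94% to 10.2% of the counts of a library. The club cell secretoglobin Scgb1a1 took 2.55% to 23.5% and the surfactant protein gene Sftpc 0.863% to 13.1%. Xist, which is transcribed from the inactive X chromosome of females, was below the Y-linked genes in flox/+ replicates 2 and 4 and in flox/flox replicate 2, and above them in the other 7 libraries. All flox/N211A libraries were in the Xist-positive class, so sex was not balanced over the genotypes. The labels do not say that replicates came from separate animals, so the p-values below measure the spread between these samples.

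**Figure D1:**
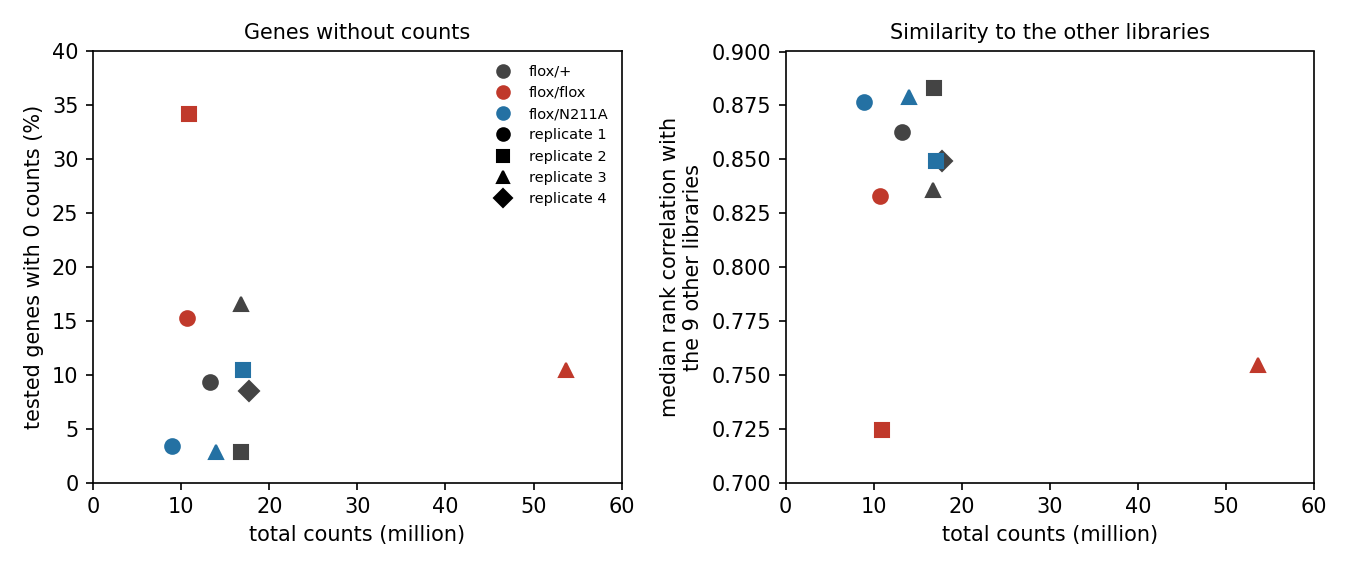
Each point is 1 library, coloured by genotype and shaped by replicate number, with total counts on the horizontal axes. The left panel shows the percentage of tested genes with 0 counts, highest in flox/flox replicate 2 at 34.2%, and the right panel shows the median rank correlation with the 9 other libraries, lowest in flox/flox replicates 2 and 3 at 0.724 and 0.755.

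Apex1 (chromosome 14, 50924968 to 50927139, GRCm38) was read first in every library. In flox/+ it stood at 4.12, 15.9, 35.9 and 54.1 CPM, scaled read counts, in replicates 1 to 4. In flox/flox it stood at 6.02 in replicate 1, at 0 counts in replicate 2 and at 0.573 in replicate 3, and in flox/N211A at 7.86, 12.9 and 6.45. Flox/flox replicate 1 therefore lay above flox/+ replicate 1, and Apex1 did not separate these 2 libraries. The means were 27.5 ± 22.1 (SD, n = 4) in flox/+, 2.20 ± 3.32 (SD, n = 3) in flox/flox and 9.07 ± 3.38 (SD, n = 3) in flox/N211A. The log2 fold change was -3.65 (SE 1.75, edgeR adjusted p = 0.353) for flox/flox against flox/+, -1.60 (SE 1.58, adjusted p = 1.00) for flox/N211A against flox/+, and 2.05 (SE 1.68, adjusted p = 0.660) for flox/N211A against flox/flox. None passed the threshold. Without flox/flox replicate 1 the first of these was -6.44 (adjusted p = 0.0992) and the last 4.84 (adjusted p = 0.165). Without flox/flox replicates 2 and 3 they were -2.19 and 0.61. Which part of the gene Cre removes is not given in the sources used here, and counts summed over the whole gene include transcript parts outside it.

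The comparison of flox/flox with flox/+ sets cells with 2 flox alleles of Apex1 against cells with 1, and how far Cre removed them in each library is not known. Genes of motile cilia were higher in flox/flox and genes of alveolar type II cells, the surfactant-producing cells of the alveolus, were lower. All 12 ciliated cell genes tested lay above 0, with a median log2 difference of 1.56, which is 2.18 above the median of all genes of -0.62. The list rose (camera adjusted p = 8.76e-07, adjusted p = 0.885 with an estimated correlation). By edgeR log2 fold changes the median of all genes was 0.056, so values relative to all genes in this comparison depend on the measure. Foxj1, the master regulator of motile ciliogenesis, stood at 174 ± 159 CPM (SD, n = 3) against 19.1 ± 10.3 (SD, n = 4). Hydin, a protein of the ciliary central pair, stood at 357 ± 148 against 76.4 ± 41.8, Ccdc39 at 373 ± 172 against 126 ± 55.2 and Rsph1, of the radial spoke, at 469 ± 135 against 168 ± 91.1. The summed level of the list was 8581 ± 2878 CPM against 3448 ± 1816. Of the 20 alveolar type II genes, 1 lay above 0, the median was -2.53, or -1.92 relative to all genes, and the list fell (camera adjusted p = 3.42e-05, adjusted p = 0.885 with an estimated correlation). Sftpc, surfactant protein C (chromosome 14, 70520949 to 70524081), stood at 16855 ± 4865 CPM against 92928 ± 46669, Chil1 at 228 ± 194 against 1611 ± 1176, Egfl6 at 7.30 ± 11.6 against 147 ± 97.3 and Cxcl15 at 725 ± 822 against 3983 ± 2716. The summed level was 33005 ± 3461 CPM in flox/flox and 137545 ± 63431 in flox/+. Adjusted over the list alone, 6 ciliated genes were higher and 9 alveolar type II genes lower, and over all genes tested none was. Club cell genes, markers of another airway cell, had a median of 0.41 and did not pass (camera adjusted p = 0.0896).

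Cytosolic ribosomal protein genes fell as a list in flox/flox. None of the 50 lay above 0, and the median was -1.11, or -0.50 relative to all genes (camera adjusted p = 4.50e-04, adjusted p = 0.885 with an estimated correlation). For lists of other genes matched on transcript length and mean expression the median was -0.0036, against -0.62 for all genes. The relative value therefore depends on the genes that the list is set against. Rplp0 stood at 448 ± 98.5 CPM (SD, n = 3) against 1221 ± 300 (SD, n = 4), Rpl6 at 183 ± 24.3 against 467 ± 107, Rpl14 at 158 ± 23.4 against 405 ± 88.9 and Rpl15 at 153 ± 67.0 against 503 ± 362. Adjusted over the list alone, 0 of the 50 passed, with 17 lower and 0 higher at an unadjusted edgeR p under 0.05. Without flox/flox replicate 3 the list's median was -0.70 (adjusted p = 0.187), and without flox/flox replicates 2 and 3 it was -0.20 (adjusted p = 0.419). In flox/flox replicate 1 alone the alveolar type II median was -1.16, and in flox/+ replicate 2 against the other flox/+ libraries it was -0.91. The summed ciliated level of flox/flox replicate 1, 5581 CPM, lay within the flox/+ range of 1277 to 5590. Over the Xist-positive libraries alone (2 of each genotype) the median was -2.17 for alveolar type II, 1.94 for ciliated and -1.16 for ribosomal protein genes. Leaving out single libraries moved the alveolar type II median between -3.31 and -1.88 and the ciliated median between 1.13 and 1.72. The list count of 3 became 8 without flox/+ replicate 3 and 6 without flox/flox replicate 3.

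By single genes, edgeR called 0 genes in flox/flox against flox/+ at an adjusted p under 0.05, and the values that follow did not pass. The 5 genes with the smallest p among those higher that met the rule for named genes were Ccdc78, a protein of the centriole-forming deuterosome, at 544 ± 268 CPM (SD, n = 3) against 75.8 ± 48.6 (SD, n = 4), Morn3 at 179 ± 69.5 against 19.2 ± 11.6, Cdhr3 at 880 ± 459 against 155 ± 73.0, Wdr63 at 289 ± 153 against 43.9 ± 16.1 and Fhad1 at 395 ± 119 against 90.7 ± 14.5. Their log2 fold changes ran from 2.12 to 3.22, each with an adjusted p of 0.132. Tnfsf9, the ligand of the T cell receptor 4-1BB (chromosome 17, 57105325 to 57107757), had 0 counts in every flox/flox library and 200 ± 281 CPM in flox/+, at least 975-fold lower with a floor of 3 counts per library (adjusted p = 0.0952). Flox/+ replicate 4 carried that mean at 607 CPM, and without it Tnfsf9 was at least 316-fold lower. Such bounds cover counting error only. Of genes with a mean of at least 20 CPM in the other libraries, flox/flox replicates 2 and 3 had 17.1% and 11.2% under 1 CPM. Tnfrsf23, a decoy receptor for TRAIL (chromosome 7, 143665809 to 143685872), had 0 counts in flox/flox and 40.3 ± 20.5 CPM in flox/+, at least 196-fold lower (adjusted p = 0.0952). Ostm1 stood at 0.0249 ± 0.0431 CPM against 24.9 ± 14.7 (adjusted p = 0.117), fibronectin Fn1 at 0.104 ± 0.0957 against 56.6 ± 59.9 and the myosin heavy chain Myh7 at 0.301 ± 0.138 against 44.9 ± 31.8 (adjusted p = 0.128 for both).

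At an unadjusted p under 0.05 edgeR gave 1942 genes in flox/flox against flox/+, 771 higher and 1171 lower, where chance gives 673. That count was 3290 without flox/flox replicate 1, 1092 with only the libraries of these 2 genotypes and 753 with voom. The libraries of the genotypes did not overlap for 10.6% of the genes, where chance gives 5.71%. DESeq2 called 1026 genes, 222 higher and 804 lower, all in the same direction as in edgeR, and 978 of them had an unadjusted edgeR p under 0.05. Without the filter on low counts edgeR called 196. The count depended on single libraries, with 399 genes (91 higher, 308 lower) without flox/flox replicate 1, 4 without flox/flox replicate 2, 11 without flox/flox replicate 3 and 1 without flox/+ replicate 2. Without flox/flox replicates 2 and 3 together it was 49, with 5 higher and 44 lower.

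Urea cycle genes, which the series title names, were examined as a list of 9, of which 7 were tested. Cps1 and Otc, the mitochondrial steps that form carbamoyl phosphate and citrulline, had at most 0.672 and 0.0249 CPM in any library. In flox/flox against flox/+ the list's median was -0.23 (camera adjusted p = 0.946, adjusted p = 0.948 with an estimated correlation) and lay 0.38 above that of all genes. The median log2 ratio of the members' mean CPM, another summary, in which 2 members stood at their bound, was -0.85. The members went both ways. Arg1, the cytosolic arginase (chromosome 10, 24915221 to 24927484), had 0 counts in the flox/flox libraries and 28.3 ± 39.6 CPM (SD, n = 4) in flox/+, at least 138-fold lower (edgeR adjusted p = 0.216) and at least 43.1-fold lower without flox/+ replicate 4, and was the 1 member that passed when adjusted over the list alone. Nags had 0 counts against 2.45 ± 3.29 CPM, and 2 of the 4 flox/+ libraries had 0 counts as well. By the means it was at least 11.9-fold lower (adjusted p = 0.323) and at least 4.58-fold lower without flox/+ replicate 1. Ass1, argininosuccinate synthase (chromosome 2, 31470207 to 31520672), stood at 50.2 ± 53.8 CPM (SD, n = 3) against 5.36 ± 5.92, with flox/+ replicate 3 at 14.2 (log2 fold change 3.23, SE 1.26, adjusted p = 0.302). Asl, the lyase that follows it (chromosome 5, 130011258 to 130029247), stood at 59.0 ± 51.1 against 34.4 ± 34.4 and Arg2, the mitochondrial arginase, at 56.4 ± 21.5 against 157 ± 94.5 (log2 fold change -1.47, SE 0.64, adjusted p = 0.317). The mitochondrial carriers Slc25a15 and Slc25a13 stood at 4.44 ± 6.50 against 8.01 ± 12.0 and at 19.8 ± 20.6 against 13.0 ± 16.9. DESeq2 called Arg1. The list's median turned positive without flox/+ replicate 2 (0.65) and without flox/flox replicate 2 (0.16), and was 0.38 over the Xist-positive libraries alone.

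**Figure D2:**
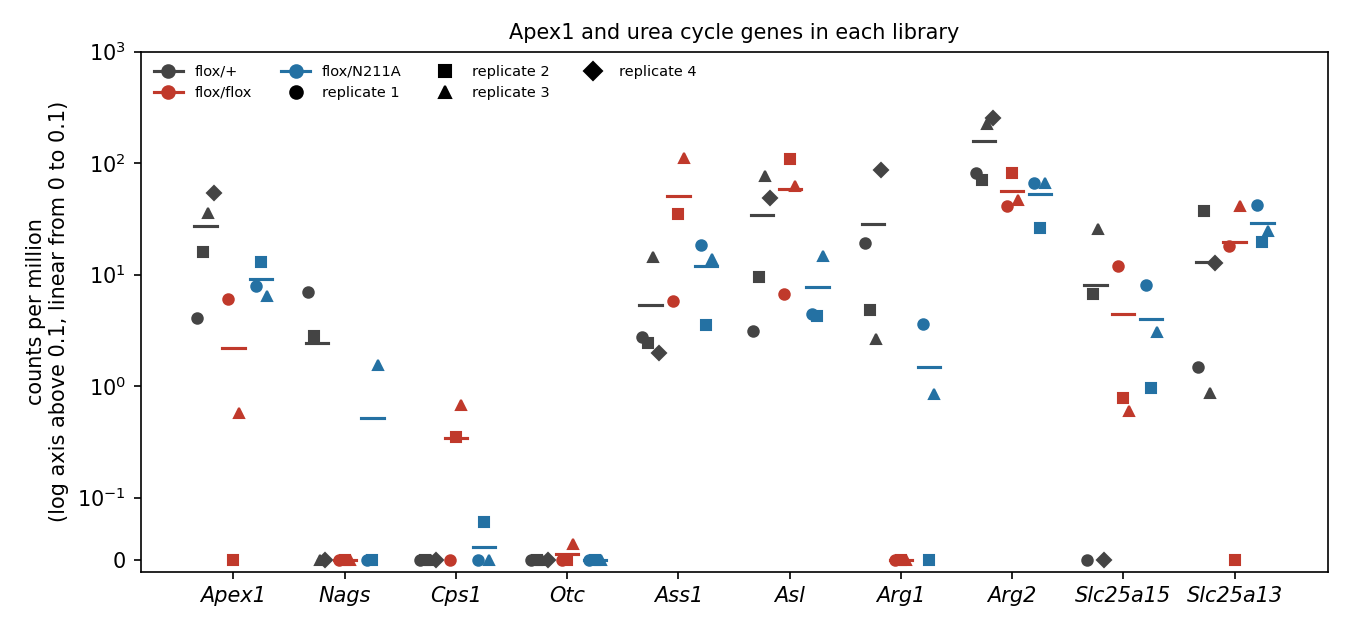
CPM of Apex1 and of the 9 urea cycle genes in each library, on an axis that is logarithmic above 0.1 and linear from 0 to 0.1. Points are libraries, coloured by genotype and shaped by replicate number, and short lines are genotype means, with Arg1 at 0 in all flox/flox libraries.

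The comparison of flox/N211A with flox/+ asks what the N211A allele changes. Camera called 9 lists. The fibroblast list held 17 genes, of which 8 had enough counts to be tested. Fibroblast genes rose, with 7 of 8 above 0 and a median of 2.47, or 2.32 relative to the median of all genes of 0.15 (adjusted p = 9.15e-04, adjusted p = 0.415 with an estimated correlation). Col1a2, a chain of type I collagen, stood at 10.1 ± 8.19 CPM (SD, n = 3) against 0.0187 ± 0.0374 (SD, n = 4), the actin-severing gelsolin Gsn at 382 ± 185 against 83.4 ± 31.8, Bgn at 31.4 ± 18.0 against 7.03 ± 6.39 and Inmt at 90.6 ± 88.7 against 20.1 ± 40.3, where flox/+ replicate 3 stood at 80.5 and the other 3 at 0 to 0.0543. Col1a2 had at most 0.0749 CPM in a flox/+ library and 0.188 in a flox/flox library. It therefore met the count filter only through flox/N211A, where it was high. The fibroblast list summed to 702 ± 387 CPM against 328 ± 118, and to 1061 ± 887 in flox/flox. Flox/N211A replicate 3, at 265 CPM, lay within the flox/+ range of 162 to 413, and replicates 1 and 2 stood at 840 and 1001. The median was 1.88 without flox/N211A replicate 1 and 3.53 without flox/N211A replicate 3. Club cell genes rose, with 11 of 12 above 0 and a median of 1.32, or 1.17 relative to all genes (adjusted p = 0.00370, adjusted p = 0.415 with an estimated correlation). Scgb1a1 (chromosome 19, 9083636 to 9087958) stood at 182388 ± 67355 CPM against 76497 ± 57698, Scgb3a2 at 5054 ± 1069 against 1769 ± 1533, Scgb3a1 at 1500 ± 2085 against 353 ± 341 and Aldh1a1 at 1153 ± 123 against 621 ± 375. Scgb3a1 was carried by flox/N211A replicate 3, without which its log2 fold change was -0.25. The club list summed to 118113, 253591 and 216108 CPM in flox/N211A replicates 1 to 3, against 31147 to 162051 in flox/+. The ciliated list had a median of 0.53 and did not pass (adjusted p = 0.148). Without flox/+ replicate 4 the club list's median was 0.87 (adjusted p = 0.0941), and without flox/N211A replicate 3 it was 1.27 (adjusted p = 0.0624).

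Alveolar type II genes fell in flox/N211A, with 1 of 20 above 0 and a median of -0.45, or -0.60 relative to all genes (camera adjusted p = 0.00245, adjusted p = 0.474 with an estimated correlation). The list summed to 57020.2 to 65554.5 CPM in flox/N211A, and flox/+ replicate 2 lay in that range at 57761. Flox/+ replicates 1, 3 and 4 stood at 132733, 212274 and 147412. Sftpc stood at 36144 ± 1825 CPM (SD, n = 3) against 92928 ± 46669 (SD, n = 4), the lysozyme Lyz2 at 4410 ± 1157 against 11736 ± 6914, Napsa at 308 ± 34.4 against 734 ± 497 and Sftpa1 at 10911 ± 1240 against 19742 ± 7963. Genes of the transitional alveolar state, which marks cells leaving the type II state, fell, with 0 of 17 above 0 and a median of -0.62 (adjusted p = 0.00193, adjusted p = 0.415 with an estimated correlation). The keratins Krt18 and Krt8 stood at 517 ± 227 against 1217 ± 720 and at 487 ± 172 against 1014 ± 578, clusterin Clu at 1614 ± 677 against 3514 ± 1092 and galectin Lgals3 at 490 ± 124 against 883 ± 345. The MHC class II genes, which present antigen, had a median of -0.96 with 1 of 9 above 0 and fell (adjusted p = 0.00618, adjusted p = 0.531 with an estimated correlation). H2-Aa stood at 378 ± 46.2 against 838 ± 499, H2-Eb1 at 134 ± 12.4 against 340 ± 250, H2-DMb1 at 27.2 ± 16.7 against 92.5 ± 67.9 and H2-DMa at 29.4 ± 5.62 against 91.0 ± 43.9. The list summed to 843 to 1071 CPM in flox/N211A, and flox/+ replicates 1 and 2 lay in that range at 899 and 1012, while flox/+ replicates 3 and 4 stood at 3648 and 3475. The transitional list did not pass without flox/N211A replicate 1 (adjusted p = 0.0557). The MHC class II list did not pass without flox/+ replicate 3 (0.0812), flox/+ replicate 4 (0.0630) or flox/N211A replicate 2 (0.133).

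Glycolysis and hypoxia genes fell in flox/N211A, with 6 of 20 above 0 and a median of -0.59 (adjusted p = 0.00245, adjusted p = 0.415 with an estimated correlation). Enolase Eno1 stood at 22.2 ± 13.3 CPM (SD, n = 3) against 250 ± 252 (SD, n = 4), Pgk1 at 16.8 ± 6.22 against 79.6 ± 35.7, Tpi1 at 89.5 ± 16.4 against 293 ± 239 and Gapdh at 7.42 ± 2.36 against 35.3 ± 28.0. Oxidative phosphorylation genes fell, with 11 of 40 above 0 and a median of -0.25 (adjusted p = 0.00245, adjusted p = 0.415 with an estimated correlation), and Uqcrc1, of respiratory complex III, and the ATP synthase subunits Atp5o and Atp5c1 were among the members with the smallest p. Ribosomal protein genes had a median of -0.15 with 21 of 50 above 0 (adjusted p = 0.0181, adjusted p = 0.663 with an estimated correlation), and Rpl15, Rplp0, Rpl6 and Rpl13 led it. Genes of arginine and polyamine metabolism outside the urea cycle had a median of -0.51 with 5 of 17 above 0 (adjusted p = 0.0280, adjusted p = 0.415 with an estimated correlation). Spermidine acetyltransferase Sat1 stood at 298 ± 17.9 against 602 ± 298, with flox/+ replicate 4 at 1049, Amd1 at 40.7 ± 19.6 against 86.4 ± 23.8, Srm at 6.67 ± 2.49 against 28.1 ± 22.8 and the arginine transporter Slc7a2 at 43.1 ± 15.2 against 14.2 ± 13.7. Oxidative phosphorylation did not pass without flox/N211A replicate 1 (adjusted p = 0.0528). The ribosomal list's median was 0.11 without flox/+ replicate 1 (0.739) and 0.017 without flox/N211A replicate 1 (0.417). The arginine and polyamine list did not pass without flox/+ replicate 1 (0.0818), 2 (0.0664) or 4 (0.0682), flox/flox replicate 2 (0.0508) or flox/N211A replicate 2 (0.128). In the last case its median was -0.031, and in the others -0.56 to -0.47. With a term for sex, 1 of the 9 lists was called, alveolar type II, while the medians of the others kept their signs, such as 2.06 for fibroblast, 1.07 for club and -0.96 for MHC class II genes. Fry called 0. Over the Xist-positive libraries alone the medians were 2.49 for fibroblast, 1.11 for club, -0.77 for alveolar type II, -0.68 for the transitional state, -1.02 for MHC class II, -0.79 for glycolysis, -0.35 for oxidative phosphorylation, -0.22 for ribosomal protein and -0.29 for arginine and polyamine genes.

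By single genes, edgeR called 0 in flox/N211A against flox/+, and every value that follows had an adjusted p of 1.00. The serine protease inhibitor gene Serpinb1a had 0 counts in flox/+ and 48.5 ± 70.4 CPM (SD, n = 3) in flox/N211A, at least 258-fold higher, and at least 41.9-fold higher without flox/N211A replicate 3, which stood at 130 CPM. Prelp, of the extracellular matrix, had 0 counts in flox/+ and 19.6 ± 17.0 CPM in flox/N211A. By the means it was at least 104-fold higher, and at least 70.9-fold higher without flox/N211A replicate 2. In flox/N211A replicate 3 Prelp stood at 0.210 CPM, the floor of 3 counts. The cytochrome P450 gene Cyp2a5 stood at 189 ± 45.7 against 37.7 ± 28.6 (SD, n = 4). Tert, the telomerase catalytic subunit (chromosome 13, 73626911 to 73649843), had 0 counts in flox/N211A and 10.3 ± 11.9 CPM in flox/+, at least 46.8-fold lower, and at least 22.2-fold lower without flox/+ replicate 1. Stathmin Stmn1 stood at 25.7 ± 4.82 against 104 ± 35.1 and Bcr at 41.8 ± 4.80 against 181 ± 112. Antizyme Oaz1, an inhibitor of polyamine synthesis, and its pseudogene Oaz1-ps each stood at 175 against 695, nearly the same value, so reads of the pair could not be told apart. At an unadjusted p under 0.05 there were 193 genes, 98 higher and 95 lower, where chance gives 673. That count depended on libraries in and outside this comparison. It was 452, 463 and 437 without flox/flox replicate 1, 2 and 3 in turn, 801 without flox/flox replicates 2 and 3, 334 without flox/+ replicate 2 and 113 without flox/+ replicate 4. With only the libraries of these 2 genotypes it was 497, and with voom 728. The libraries did not overlap for 6.14% of the genes, where chance gives 5.71%. DESeq2 called 16 genes, 9 higher and 7 lower, of which 13 had 0 counts in all libraries of 1 genotype, and edgeR without the low-count filter called 13. Adjusted over the list alone, 1 fibroblast gene, Col1a2, was higher, and no member of the other 8 lists passed. The urea cycle list had a median of -1.37, or -1.51 relative to all genes (camera adjusted p = 0.172, adjusted p = 0.415 with an estimated correlation), with a mean of -0.48. The median log2 ratio of mean CPM was -1.58, with no member at a bound, and the list's median was -1.25 over the Xist-positive libraries alone. Arg2 stood at 52.6 ± 23.1 CPM against 157 ± 94.5 (log2 fold change -1.58, SE 0.64), Asl at 7.78 ± 5.95 against 34.4 ± 34.4, Arg1 at 1.49 ± 1.89 against 28.3 ± 39.6, Nags at 0.514 ± 0.890 against 2.45 ± 3.29, Ass1 at 11.9 ± 7.55 against 5.36 ± 5.92, Slc25a15 at 4.03 ± 3.64 against 8.01 ± 12.0 and Slc25a13 at 28.8 ± 11.9 against 13.0 ± 16.9. Its unadjusted camera p of 0.0638 became less than 0.05 without flox/+ replicate 1 (0.0360), flox/+ replicate 4 (0.0431), flox/N211A replicate 1 (0.0363) or flox/N211A replicate 3 (0.0369). The median was -0.30 without flox/+ replicate 2.

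**Figure D3:**
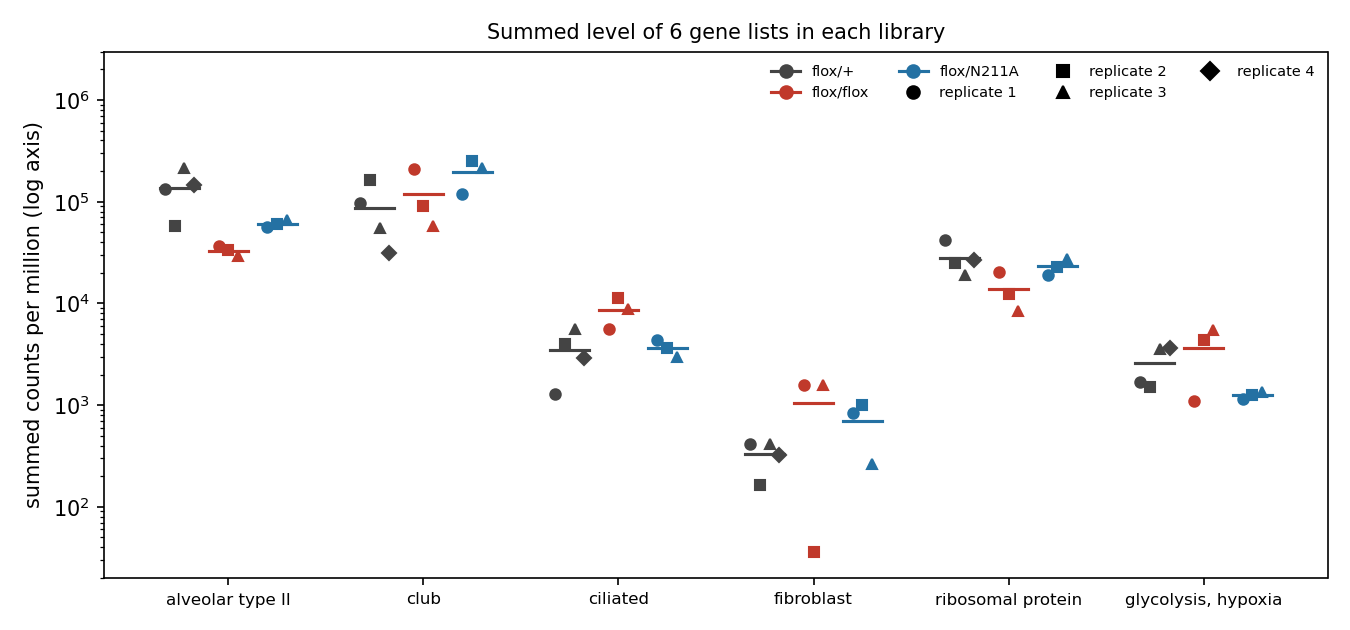
Summed CPM of 6 gene lists in each library on a log axis. Points are libraries, coloured by genotype and shaped by replicate number, and short lines are genotype means. Alveolar type II genes averaged 137545 in flox/+, 33005 in flox/flox and 60839 in flox/N211A.

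The comparison of flox/N211A with flox/flox is also the test of the difference between the comparisons above. Ciliated genes fell in flox/N211A against flox/flox, with 0 of 12 above 0 and a median of -1.08, or -1.93 relative to the median of all genes of 0.85 (camera adjusted p = 2.21e-04, adjusted p = 0.865 with an estimated correlation). Rsph1 stood at 133 ± 18.8 CPM (SD, n = 3) against 469 ± 135 (SD, n = 3), Tppp3 at 482 ± 52.2 against 2929 ± 2296, Hydin at 133 ± 50.9 against 357 ± 148 and Foxj1 at 47.1 ± 17.3 against 174 ± 159. Glycolysis and hypoxia genes fell, with 6 of 20 above 0 and a median of -0.76, or -1.60 relative to all genes (adjusted p = 0.0173, adjusted p = 0.865 with an estimated correlation). Ankrd37, a hypoxia-induced gene, stood at 17.1 ± 6.88 against 158 ± 126, Pgk1 at 16.8 ± 6.22 against 97.9 ± 63.9, Eno1 at 22.2 ± 13.3 against 297 ± 246 and Aldoa at 323 ± 33.8 against 1156 ± 776. Alveolar type II genes rose, with 19 of 20 above 0 and a median of 1.79, or 0.94 relative to all genes (adjusted p = 0.0431, adjusted p = 0.865 with an estimated correlation). Cxcl15 stood at 3162 ± 900 against 725 ± 822, Egfl6 at 83.1 ± 38.4 against 7.30 ± 11.6, S100g at 174 ± 84.7 against 23.6 ± 23.4 and Chil1 at 717 ± 60.9 against 228 ± 194. Adjusted over the list alone, 2 ciliated and 3 glycolysis genes were lower and 0 alveolar type II genes passed. Over the Xist-positive libraries alone (3 and 2) the medians were -1.19 for ciliated, -1.02 for glycolysis and 1.43 for alveolar type II genes.

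The ciliated call held with any 1 library left out (median -1.20 to -0.86, highest adjusted p = 0.00675), and the other 2 calls did not. Without flox/flox replicate 3 the glycolysis median was 0.089 (adjusted p = 0.187). The alveolar type II call was lost without flox/+ replicate 1 (0.0659), 3 (0.0858) or 4 (0.0623), flox/flox replicate 2 (0.0914) or 3 (0.0872), and flox/N211A replicate 2 (0.0898) or 3 (0.0694). Without flox/flox replicates 2 and 3 together, 0 lists were called, with adjusted p = 0.0807 and a median of -0.94 for ciliated, 0.806 and 0.34 for glycolysis, and 0.589 and 0.73 for alveolar type II genes. The list count was 6 without flox/flox replicate 1 and 5 without flox/N211A replicate 1. The urea cycle list had a median of 0.62 and a mean of 0.44, while camera, which compares it with the other genes, gave the opposite direction (adjusted p = 0.587, adjusted p = 0.865 with an estimated correlation). The median log2 ratio of mean CPM had the other sign, -0.10, with 2 members at their bound. The list's median was -0.13 without flox/flox replicate 3 and -0.092 without flox/N211A replicate 1, and 0.05 over the Xist-positive libraries alone. Asl stood at 7.78 ± 5.95 CPM (SD, n = 3) against 59.0 ± 51.1 (SD, n = 3) and Ass1 at 11.9 ± 7.55 against 50.2 ± 53.8. Arg1 stood at 1.49 ± 1.89 against 0 counts, and 1 of the 3 flox/N211A libraries had 0 counts as well. By the means Arg1 was at least 7.22-fold higher, and at least 2.05-fold higher without flox/N211A replicate 1.

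By single genes, edgeR called 0 in flox/N211A against flox/flox, and these values did not pass. Ostm1 (chromosome 10, 42583822 to 42702459), which is needed for bone resorption and lysosome function, stood at 50.2 ± 17.1 CPM (SD, n = 3) against 0.0249 ± 0.0431 (SD, n = 3, adjusted p = 0.178). Tnfrsf23 stood at 15.2 ± 6.15 against 0 counts, at least 73.8-fold higher (adjusted p = 0.238). The imprinted gene Impact stood at 38.2 ± 17.1 against 0.0996 ± 0.173, Myh7 at 25.4 ± 7.92 against 0.301 ± 0.138 and B3gat2 at 56.2 ± 7.37 against 0.378 ± 0.425 (adjusted p = 0.266 for each). Among the lower ones, Morn3 stood at 16.5 ± 5.29 against 179 ± 69.5 and Ccdc78 at 78.6 ± 12.1 against 544 ± 268. Muc20 stood at 19.7 ± 7.03 against 252 ± 201, Spata17 at 34.6 ± 16.1 against 231 ± 137 and Plekhb1 at 112 ± 6.15 against 515 ± 285. At an unadjusted p under 0.05 there were 1622 genes, 1027 higher and 595 lower, where chance gives 673. That count was 3174 without flox/flox replicate 1, 945 without flox/N211A replicate 1, 922 with only the libraries of these 2 genotypes and 632 with voom. The libraries did not overlap for 18.6% of the genes, where chance gives 10%. DESeq2 called 667 genes, 576 higher and 91 lower, and edgeR without the low-count filter called 96. The edgeR count was 244 (33 of them lower) without flox/flox replicate 1, 2 without flox/flox replicate 2, 6 without flox/flox replicate 3 and 16 without flox/flox replicates 2 and 3.

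Flox/flox and flox/N211A were each compared with the same 4 flox/+ libraries, and edgeR called 0 genes in both, against 10 with DESeq2 (8 higher, 2 lower). At an unadjusted edgeR p under 0.05, 90 genes went in the same direction in both, and independent lists would share 13.9. Simulations that drew all 10 libraries anew, controls included, with no difference between genotypes gave 137 (114 to 156). Across genes, which are not independent replicates, the log2 differences had a correlation of 0.297 and a covariance of 0.733. The simulated values were 0.427 (0.412 to 0.439) and 0.956 (0.905 to 1.00), so the observed covariance differed from the simulated one by -0.223. The simulation gave every genotype the same dispersion for a gene. Rank correlations within flox/flox were 0.671 to 0.740, against 0.836 to 0.914 within the other genotypes. The simulated values therefore do not decide whether flox/flox and flox/N211A share fewer changes than unchanged groups would. With the 4 controls split 2 and 2 in each of the 6 ways, the correlation ran from -0.115 to 0.0876, the covariance from -0.444 to 0.244, and 0 genes were shared.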

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

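The 3 tests on the libraries that stand apart were chosen after the result was seen, and the counts over other splits of the samples before.

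Of 98 values checked in the 4 flox/+ libraries, 4 had 1 library beyond the critical value of Dixon's test for 4 samples, and chance flags about 1 in 20. Ass1 stood at 14.2 CPM in flox/+ replicate 3, against 1.999 to 2.77 in the other 3. Inmt stood at 80.5 CPM in flox/+ replicate 3, against 0 to 0.0543. Sat1 stood at 1049 CPM in flox/+ replicate 4, against 446 to 460. Col1a2 stood at 0.0749 CPM in flox/+ replicate 1, a single count, against 0 in the others.

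Flox/flox replicates 2 and 3 stood apart from the other 8 libraries. Of the genes with a mean of at least 20 CPM in the other libraries, 17.1% stayed under 1 CPM in replicate 2 and 11.2% in replicate 3, against at most 3.26% elsewhere. Fewer distinct molecules would give this, but so would any other cause that sets a library apart, so the values restate the pattern more than they explain it. The rank correlation of the 2 libraries with each other, 0.671, lay below the median of 0.740 of their correlations with the other genotypes. Loss of different genes in each library would also lower the first value. It therefore does not decide on a shared effect of the genotype as the whole cause. Sex is argued against, since 1 of the 2 had Y-linked genes above Xist. The cause stays open, an effect of the genotype included.

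Other splits of the same samples into groups of the same sizes were fitted for each comparison. Where the real split called 0 genes, every split gives at least as many, so that comparison says nothing about chance. This holds for flox/flox against flox/+ (35 of 35 splits, highest other 1), for flox/N211A against flox/+ (35 of 35, highest other 0) and for flox/N211A against flox/flox (10 splits, highest other 0). For flox/flox against flox/+, at an unadjusted p under 0.05, 2 of the 35 gave 1942 genes or more, and the other was 2187, so chance is not excluded. That split set flox/+ replicate 3 with flox/flox replicates 2 and 3, the libraries that stand apart, against the rest. What its count rests on was not tested. In the count of called lists, 22 of 35 splits reached the real 3, with 9 as the highest other. For flox/N211A against flox/+, 14 of 35 gave at least 193 genes at an unadjusted p under 0.05 (highest other 543) and 8 gave at least 9 lists (highest other 11). Chance is therefore not excluded for the list counts and the counts at an unadjusted p of these 2 comparisons. For flox/N211A against flox/flox the 10 splits are too few for a share under 0.05. The real values were 1622 genes at an unadjusted p under 0.05 and 3 lists, and the highest others were 1182 and 7.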

How the results depend on the processing

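Leaving out flox/flox replicates 2 and 3 together, and the terms for sex and genes detected in the tests of lists, were tests chosen after the result was seen. The other alternatives were fixed before. The cause of a changed value was not tested unless stated. Which lists are followed here and reading a list's direction from its median were also decided after the result was seen.

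For single genes and single lists, 2658 values were computed under alternatives, of which 2437 kept their result, 69 were weaker, 118 passed a threshold that they had missed and 34 changed sign. For the counts, the urea cycle list and the shared genes, 171 of 221 kept their result, 5 passed a threshold, 9 changed sign and 36 moved. Of 112 named gene values, 12 changed sign in at least 1 of 2329 alternatives, 30 times in all and 2 times under other scalings.

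The number of genes called in flox/flox against flox/+, 0 with edgeR, was 1026 with DESeq2, 196 without the low-count filter, 2 at an adjusted p under 0.1, 49 without flox/flox replicates 2 and 3, and 0 to 399 with 1 library left out. For flox/N211A against flox/+ it was 16 with DESeq2 and 13 without the filter. For flox/N211A against flox/flox it was 667 with DESeq2, 96 without the filter, 16 without flox/flox replicates 2 and 3, and 0 to 244 with 1 library left out. Genes called against flox/+ in both other genotypes numbered 10 with DESeq2 and 7 without the filter. DESeq2's larger counts include 157, 13 and 124 genes with 0 counts in all libraries of 1 genotype.

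The 3 lists called in flox/flox against flox/+ became 0 with an estimated correlation, 8 without the low-count filter, 6 with the stricter filter, which tested 27 lists, 5 without flox/flox replicates 2 and 3, and 3 to 8 with 1 library left out. Fry did not call the ribosomal protein list there (adjusted p = 0.102). The 9 called in flox/N211A against flox/+ became 0 with an estimated correlation, 0 with fry and 1 with a term for sex. With that term the medians kept their signs, at 2.06 for fibroblast, 1.07 for club, -0.96 for MHC class II and -0.88 for glycolysis genes. They were -0.57 for arginine and polyamine, -0.44 for transitional, -0.27 for oxidative phosphorylation and -0.21 for ribosomal protein genes. All flox/N211A libraries were Xist-positive, so the term was estimated from the other genotypes. These values therefore do not decide on sex as the cause of the lost calls. A term for genes detected ended the calls of the oxidative phosphorylation (median -0.23, adjusted p = 0.150), ribosomal protein (-0.028, 0.310) and arginine and polyamine lists (-0.61, 0.106), and the stricter filter that of the last (-0.50, 0.109). Of these medians only that of the ribosomal protein list came near 0. With 1 library left out the medians ran from 1.88 to 3.53 for fibroblast, 0.87 to 1.82 for club, -0.63 to -0.40 for alveolar type II, -0.88 to -0.48 for transitional, -1.26 to -0.60 for MHC class II, -0.74 to -0.44 for glycolysis, -0.34 to -0.16 for oxidative phosphorylation and -0.83 to -0.031 for arginine and polyamine genes. The 3 called in flox/N211A against flox/flox became 0 with an estimated correlation, 0 with fry, 5 without the filter, 7 with the stricter filter, 5 with only the 2 genotypes compared, 0 without flox/flox replicates 2 and 3, and 2 to 6 with 1 library left out. The alveolar type II call there was also lost with a prior count of 0.5 (adjusted p = 0.0597) and with a term for sex (0.139), while its median stayed at 1.79 and 1.76. It ran from 1.22 to 2.55 with 1 library left out.

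The urea cycle list's median in flox/flox against flox/+ was 0.093 without the low-count filter, 0.20 with only the 2 genotypes compared, 0.62 with a term for genes detected, and -1.18 to 0.65 with 1 library left out. It ran from -1.69 to -0.30 with 1 library left out in flox/N211A against flox/+, with camera p from 0.0360 to 0.314. In flox/N211A against flox/flox it was -0.093 without the filter, -0.0060 with only the 2 genotypes compared, and -0.13 to 1.36 with 1 library left out. The direction of this list in either comparison with flox/flox could therefore go either way.

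Replicate numbers were checked for pairing. Of 9 pairs with the same number, 0 had a residual correlation over 0.1 (range -0.065 to 0.098), and 3 of 10 libraries matched best with their own number, so the libraries were not taken as paired. With the replicate number as a block, 1 gene was called in flox/flox against flox/+, the urea cycle median in flox/N211A against flox/+ was -1.01 and passed an unadjusted threshold of 0.05 in camera, and Slc25a15 in flox/N211A against flox/flox was 0.24. The block ended the calls of the club (median 0.87, adjusted p = 0.111) and arginine and polyamine lists (0.0627) in flox/N211A against flox/+, and of alveolar type II genes in flox/N211A against flox/flox (0.0521). At an unadjusted p under 0.05 it gave 947, 94 and 930 genes, against 1942, 193 and 1622 without it.

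Some log2 fold changes changed sign. In flox/flox against flox/+, Asl was -2.36 without flox/flox replicates 2 and 3. Slc25a15 was 2.08 with voom, 0.58 without those 2 libraries, and -3.52 to 1.00 with 1 library left out, and Slc25a13 was -0.94 with voom and -0.53 to 1.88. In flox/N211A against flox/+, the ribosomal protein list's median ran from -0.31 to 0.11 with 1 library left out. Slc25a15 was 2.64 with voom and -1.98 to 0.86 with 1 library left out, and Scgb3a1 ran from -0.25 to 2.68.

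In flox/N211A against flox/flox without flox/flox replicates 2 and 3, the glycolysis list's median was 0.34, Ass1 1.06, Asl 0.22, Arg2 0.37, Eno1 0.58 and Aldoa 0.31, so the direction of these values may rest on those 2 libraries. With 1 library left out the glycolysis median ran from -1.24 to 0.089. Arg2 was 0.11 with totals only, 0.18 with voom, 0.026 with only the 2 genotypes compared, 0.19 with a term for genes detected, 0.082 with a term for sex, and -0.30 to 0.24 with 1 library left out. Slc25a15 was 0.091 with totals only, 0.57 with voom, 0.58 with a term for genes detected, and -1.13 to 2.53 with 1 library left out. Slc25a13 was -0.64 with a term for genes detected, and -0.060 to 1.68 with 1 library left out.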

Other observations

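The test on short transcripts was fixed before its result was seen, and all other tests of explanations below and the genes named in the next paragraph were chosen after.

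Genes of the integrated stress response, driven by the factor ATF4, had 3 of 20 above 0 in flox/flox against flox/+ and a median of -1.26, or -0.64 relative to all genes (fry adjusted p = 0.0366, camera adjusted p = 0.107, adjusted p = 0.885 with an estimated correlation). Their summed level went the other way, 4066 ± 3810 CPM in flox/flox against 2736 ± 636, with flox/flox replicate 2 at 8465 and replicates 1 and 3 at 1781 and 1952. Psat1, of serine synthesis, stood at 0.0314 ± 0.0543 CPM in flox/flox, 27.6 ± 27.0 in flox/+ and 26.0 ± 13.3 in flox/N211A. The mitochondrial folate enzyme Mthfd2 stood at 0.199 ± 0.345 against 24.1 ± 18.8 in flox/+, and the alanyl-tRNA synthetase Aars at 0.221 ± 0.301 against 23.7 ± 19.3. Adjusted over the list alone 3 members were lower, and over all genes tested none was. Transcriptional targets of MAPK signalling had 2 of 19 above 0 and a median of -1.23, or -0.62 relative to all genes (fry adjusted p = 0.0366, camera adjusted p = 0.0738, adjusted p = 0.885 with an estimated correlation), and summed to 861 ± 124 CPM against 1631 ± 366. In flox/N211A against flox/+ the median of the stress response list was -0.23, with a mean of 0.087, and that of the MAPK list -0.022. Genes with G-quadruplexes in their promoters, a DNA structure that the series title names, had a median of -1.36, or -0.75 relative to all genes, in flox/flox against flox/+ with 5 of 12 above 0 (camera adjusted p = 0.577). Among them Src stood at 0.837 ± 1.13 CPM in flox/flox, 24.9 ± 8.17 in flox/+ and 36.8 ± 8.28 in flox/N211A. MHC class I genes had a median of 0.67, or 1.28 relative to all genes (camera adjusted p = 0.0572), with H2-T23 at 297 ± 118 CPM against 84.3 ± 29.9. In the same libraries flox/flox replicates 2 and 3 had 17.1% and 11.2% of well expressed genes under 1 CPM.

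Alveolar type II genes were lower in both flox/flox and flox/N211A than in flox/+, with ciliated genes higher in the first and club genes in the second. A smaller share of alveolar cells would raise all other cell types alike. The mean log2 CPM of ciliated minus club genes differed from flox/+ by -0.893 in flox/N211A, within the 1.21 SD of the flox/+ libraries. The medians of other markers relative to all genes ran from 2.32 (fibroblast) over 0.17 (alveolar type I) to -0.74 (neutrophil) and -1.79 (erythroid). The last 2 lists varied strongly between flox/N211A libraries, with sums of 13.3 to 213 CPM (neutrophil) and 0.841 to 2793 (erythroid). Whether the share alone differed stays open. In flox/flox the difference of ciliated minus club genes was 1.25, close to that SD. The relative medians ran from 2.18 (ciliated) over 1.03 (club) and 0.012 (fibroblast) to -1.02 (alveolar type I), -1.50 (endothelial) and -2.05 (leukocyte). An even rise was not seen there, and the explanation stays open. The median of alveolar type II genes in flox/flox replicate 1 was -1.16, little beyond single flox/+ libraries against the other 3 (-0.91 to 0.37). The summed level in flox/flox replicate 1 was 36339 CPM, below the flox/+ range of 57761 to 212274. Both values rest on 1 library, so flox/flox replicates 2 and 3 as the whole cause stay open. Over the Xist-positive libraries, 2 of them flox/+, the flox/N211A median was -0.77. The summed levels of these libraries were 132733 and 212274 CPM in flox/+ and 57020.2 to 65554.5 in flox/N211A. The fall thus remained among libraries of the same sex class. This argues against sex as its whole cause in flox/N211A, though only 2 flox/+ libraries enter. The median itself lies within the -0.91 to 0.37 of single flox/+ libraries, of which -0.91 is replicate 2, with Y-linked genes above Xist. How the cells were chosen is not given in the sources used here, and an effect of the genotype on the cells stays open.

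Ribosomal protein genes were lower in flox/flox. The list's median of -1.11 lay below the 5th percentile of -0.20 of 10000 lists matched on transcript length and mean expression. Length was that of the longest annotated transcript of a gene, with a median of 1139.5 bases in the list. This need not be the transcript expressed, so loss of short transcripts stays open. The median was -0.198 in flox/flox replicate 1 alone, within the -0.74 to 1.02 of single flox/+ libraries against the other 3, so the lower level may rest on flox/flox replicates 2 and 3. Without these 2 libraries the list did not pass (adjusted p = 0.419), and whether the genotype lowers it stays open.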
